A study of Arabidopsis thaliana with 9 samples.

How the data were processed

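RNA from whole Arabidopsis thaliana plants, 21 days old, was hybridised to whole-transcript Affymetrix arrays, with 9 arrays in 3 groups of 3. Per the labels, one group received the solvent acetone alone (control), another 2,5-dichlorobiphenyl (2,5-DCB) at 50 mg per L and the other its 4'-hydroxylated form (4'-OH-2,5-DCB) at 5 mg per L, all in the nutrient medium. The groups and replicate numbers were taken from the sample titles and characteristics. Nothing in the labels says which plants or boxes each array came from, so the p-values measure only the spread between these arrays, which may be technical.

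The deposited values are log2 signals, 1 per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. The version, the summarization method and the background correction are not given in the sources used here. The value table held 38408 probe sets on 9 arrays with 0 missing values and 0 further sample columns, and no further normalization was applied in the main fit. The platform annotation was used to name probe sets, and 17481 of them were listed in it. Of these, 16722 were paired with 1 gene and 759 with several genes, and the other 20927 are unnamed here. Only probe sets with 1 gene were tested, and they stand for 16550 genes, of which 146 have more than 1 probe set. Symbols were updated through gene IDs with the RefSeq table of the assembly TAIR10.1: 16574 probe sets matched, and 148 kept the name in the annotation. The tested genes include 16406 of the 27562 protein-coding genes in that table (59.5%). No coordinates are printed, since the genome build behind the probe sets is not given in the sources used here.

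All 9 arrays were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, with 1 term per group, so that the 3 groups share one estimate of the spread. Contrasts were 2,5-DCB minus control, 4'-OH-2,5-DCB minus control and 4'-OH-2,5-DCB minus 2,5-DCB, plus a moderated F-test over the 3 groups. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, in a two-sided test. For each comparison with control, the named genes are the 10 called rises and the 10 called falls of largest size among those whose 3 exposed arrays all lie beyond the 3 control arrays. For the contrast of the exposures the number is 5 per direction, and where none passes, the 5 smallest p-values per direction are named and said not to have passed. From each gene list, members with the smallest p-values are named. A probe set paired with several genes is never named. These rules, the tests, 38 gene lists and the alternatives were fixed before the data were examined.

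The lists were tested with camera, at the preset inter-gene correlation of 0.01, over 1 probe set per gene (the brightest). Few list members are named by the annotation: 12 lists held 3 or more tested genes, 19 held 1 or 2 and 7 held 0. A minimum of 3 tested genes for the list test, and the limit of the lists to nuclear genes, were set after the coverage and values had been seen. Both were undone in added alternatives. The 36 list tests were adjusted together. A list of touch and wound genes and a scan of 54 gene families by symbol were likewise added after the largest changes had been seen.

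Alternatives were quantile normalization, centring of array medians, removal of probe sets with a mean under the 25th or the 50th percentile, all probe sets, only the arrays of the groups compared, eBayes with trend and robust options, array weights, minimum changes of 2 times, the replicate number as a block, fry and camera with an estimated correlation for lists, and leaving out each array in turn. The correlation and covariance that the shared control arrays add to the comparisons with control were estimated from 100 simulations of unchanged groups. These make almost no calls, so they give no reference for the overlap of the called genes. The controls were not split, since 3 arrays cannot give 2 sets of 2.

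The fit was tested on simulated data with the spreads of the 16722 probe sets and 200 changed probe sets per exposure. For 2,5-DCB, 30 of 67 probe sets changed by 1 on the log2 scale were recovered, 55 of 67 changed by 2 and 63 of 66 changed by 3, with 4 false calls. For 4'-OH-2,5-DCB, 27 of 67, 61 of 67 and 60 of 66 were recovered, with 6 false calls. The simulation drew independent errors, so it leaves out any distortion shared by the probe sets of one array.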

Results

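The series measured transcript levels in whole Arabidopsis plants grown with a dichlorobiphenyl (2,5-DCB), with its 4'-hydroxylated form (4'-OH-2,5-DCB), or with the solvent alone. Each group had 3 arrays. The dose was 50 mg per L for 2,5-DCB and 5 mg per L for 4'-OH-2,5-DCB, so the groups differ in dose as well as in the hydroxyl group. Median log2 signals of the tested probe sets lay between 4.69 and 4.91. The array of 4'-OH-2,5-DCB replicate 1 had a narrower range than the rest, with an SD across probe sets of 1.68 against 2.128 to 2.203 on the other 8 arrays. Its highest correlation with another array was 0.927, whereas the other 8 correlated with each other at 0.956 or above (Pearson r across probe sets, which are not independent replicates). This array weighs on every count below, since all 9 arrays share one estimate of spread.

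**Figure D1:**
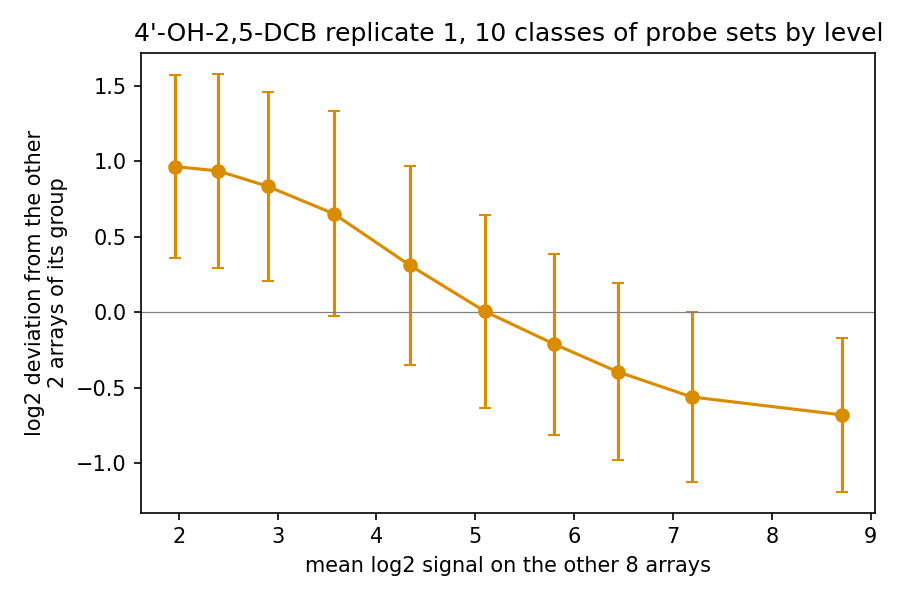
Mean log2 deviation of 4'-OH-2,5-DCB replicate 1 from the other 2 arrays of its group (vertical axis; bars, SD across probe sets) against the mean log2 signal on the other 8 arrays (horizontal axis), for 10 equal classes of probe sets by level. The dimmest class lay 0.96 above and the brightest 0.68 below the other arrays of the group.

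The first comparison asked which genes change under 2,5-DCB. PUB19, a U-box ubiquitin ligase, fell most, from 7.69 ± 0.74 to 2.97 ± 0.27 (mean log2 signal ± SD, n = 3 each), which is 26.3-fold. The cold and dehydration genes COR15A, COR15B, KIN2 and COR47 fell by 2.91, 2.18, 2.88 and 1.52 on the log2 scale, and the transcription factor gene ORA47 fell by 3.14. AT5G39120 rose from 2.54 ± 1.01 to 6.87 ± 0.17 (20.2-fold), the largest measured rise, and its neighbour by locus number AT5G39110 rose 8.37-fold. The 25th percentile of probe sets lay at 2.80 to 3.01 on the control arrays and 2.89 to 2.95 on those of 2,5-DCB, so the dim side of AT5G39120 and of PUB19 may be background, and their folds and ranks are uncertain. CHI (AT2G43570), a putative chitinase gene, rose 13.6-fold and the plant defensin gene PDF1.2 rose 9.25-fold. In limma, 777 probe sets passed an adjusted p of 0.05, 305 higher and 472 lower, and 578 of them changed at least 2-fold.

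Further falls under 2,5-DCB were those of AT5G13181 (log2 change -4.24, SE 0.36), AT1G80865 (-4.06, SE 0.24), AT5G15660 (-3.68), AT2G34930 (-3.47), AT1G73510 (-3.33), PRA1.C (-3.21), AT1G01130 (-3.17) and AT5G45450 (-3.07). Of these, AT1G80865 had the smallest limma adjusted p of the comparison, 0.000428. The means of AT5G13181 and AT5G45450 under 2,5-DCB lay below the 25th percentile of those arrays. Their dim side may therefore be background, and the size of their falls is uncertain. Further rises were those of AT1G26240 (3.49), AT1G51920 (3.04), AT3G47480 (3.03), AT1G27020 (2.95), AT1G51860 (2.94) and the peroxidase gene Prx37 (2.87, SE 0.33, adjusted p 0.00303). The adjusted p of PDF1.2 was 0.0419, and became 0.0515 after quantile normalization. With 1 array left out, PDF1.2, AT1G27020, AT1G51860, CHI, AT1G26240 and AT3G47480 lost the call in at least 1 case, with adjusted p-values of up to 0.141, 0.119, 0.0984, 0.0875, 0.0644 and 0.0597.

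In the abscisic acid and dehydration list, 5 of 6 tested genes were lower and 0 higher under 2,5-DCB (5 lower adjusted over the list alone), with a median log2 change of -1.85. KIN1 fell 2.83-fold (adjusted p 0.0175), while the dehydrin gene LTI30, at -1.13, did not pass (adjusted p 0.462). The camera adjusted p of the list was 1.96e-08, and adjusted p = 0.211 with an estimated correlation. Of 55 UDP-glycosyltransferase genes, which attach sugars to small molecules, 6 were higher and 0 lower (8 higher adjusted over the list alone): UGT72E2 (2.39), UGT87A2 (2.09), UGT76B1 (1.90), UGT73B4 (1.49), UGT73B2 (1.42) and UGT84A3 (1.18). Its camera adjusted p was 0.0264 (adjusted p = 0.336 with an estimated correlation, and 0.0612, 0.0566 and 0.0855 without 4'-OH-2,5-DCB replicate 1, control replicate 3 or 2,5-DCB replicate 3), and its median of 0.17 was 0.101 without control replicate 3. In the xenobiotic response list 1 of 4 tested genes was higher, UGT73B4, and all 4 also belong to the glycosyltransferase or glutathione transferase lists (2 higher adjusted over the list alone, camera adjusted p 0.0108, adjusted p = 0.336 with an estimated correlation). In the light harvesting and photosystem list 1 of 8 tested genes was lower, LHCB4.2 at -0.95, and the median was -0.56 (2 lower adjusted over the list alone, camera adjusted p 0.00969, adjusted p = 0.429 with an estimated correlation). Of these 8 genes 5 were lower, and of the 4 xenobiotic response genes 2 were higher, without 4'-OH-2,5-DCB replicate 1.

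Other lists under 2,5-DCB did not pass the list test. The tau glutathione S-transferases had 0 called of 11 (1 lower adjusted over the list alone) and the phi class 0 of 3 (1 higher and 1 lower adjusted over the list alone). Of 240 cytochrome P450 genes in the list only 24 were tested, mostly of the CYP71B subfamily, so the result does not cover the rest. Of these 24 genes 1 was higher, CYP71B6 (1.28), and 2 adjusted over the list alone. In the auxin list 2 of 9 genes were lower, WES1 (-1.52) and IAA29 (-2.32), and in the expansin and xyloglucan hydrolase list 2 of 28 were lower, EXPA8 (-2.31) and EXPB1 (-1.60). Adjusted over the list alone 2 auxin genes and 3 expansin list genes were lower. Without 4'-OH-2,5-DCB replicate 1, 5 expansin list genes were lower, 2 P450 genes higher and 2 lower, 1 tau gene lower, 2 unfolded protein response genes higher and 1 lower, 1 root marker higher and 1 flower marker lower. The medians of the auxin and expansin lists, 0.08 and 0.05, were above 0 although their means, -0.28 and -0.15, and the direction of the test were below; with 1 array left out the medians ranged from 0.0538 to 0.119 and from -0.0328 to 0.079. The tau median was near 0, with its mean and test below, and the phi median and test were below 0 with its mean above. Root markers had 0 called of 4 (median 0.32), flower and pollen markers 0 of 3 (median -0.84) and the unfolded protein response 0 of 3 (median 0.91). Adjusted over the list alone 1, 0 and 2 were called, all higher. The root marker median ranged from 0.188 to 0.439 with 1 array left out. The flower and pollen list passed without control replicate 1 (median -1.47, camera adjusted p 0.0238), and its median was -0.47 without control replicate 2. Among lists with 1 or 2 tested genes, which had no list test, the senescence regulator gene WRKY6 rose by 1.90, the FK506-binding protein gene AT5G48570 by 1.13 and the seed storage gene PAP85 by 1.71, while the efflux carrier gene AT5G52050 fell by 2.31.

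The count of 777 rested on which arrays entered. Without 4'-OH-2,5-DCB replicate 1 it was 2161 (990 higher and 1171 lower), which held all 777. The balance moved with the setting, to 326 higher and 708 lower after quantile normalization and to 64 and 196 without 2,5-DCB replicate 3. With all probe sets it was 627 and 690, where repeated values among unnamed probe sets were counted (735 called, 597 distinct rows). The count was 399, 181 and 340 without control replicate 1, 2 or 3, and 432, 204 and 260 without 2,5-DCB replicate 1, 2 or 3.

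The second comparison asked which genes change under 4'-OH-2,5-DCB. PUB19 again fell most, to 3.62 ± 0.35 from 7.69 ± 0.74 in the control (16.8-fold), and COR15A fell by 3.37, COR15B by 2.96, KIN2 by 2.70 and COR47 by 2.02 on the log2 scale. AT5G39120 rose 27.4-fold to 7.31 ± 0.32, from the same dim control level. The defensin genes PDF1.2b, PDF1.2 and PDF2.5 rose 14.4-fold, 12.2-fold and 4.58-fold, and the beta-glucosidase gene BGLU21 rose 5.37-fold. The adjusted p of PDF1.2 was 0.0353, and 0.0511 without 4'-OH-2,5-DCB replicate 1. In limma 486 probe sets passed, 168 higher and 318 lower, and 378 of them changed at least 2-fold. PDF1.2 and PDF1.2b are close paralogs, as are COR15A and COR15B, and KIN1 and KIN2, so their probe sets may not measure them separately.

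Further falls were those of AT1G80865 (-3.35), AT5G13181 (-3.30), AT5G15660 (-3.23), AT1G73510 (-3.12), AT4G28140 (-2.93), AT2G34930 (-2.89) and PRA1.C (-2.89). The smallest adjusted p, 0.00111, belonged among others to COR15B (SE 0.21) and AT1G80865 (SE 0.24). Further rises were those of AT5G39110 (2.85), AT5G26260 (2.56), AT5G23830 (2.41), AT2G16005 (2.18) and AT3G46280 (2.17). With 1 array left out, AT2G16005, PDF1.2, AT3G46280, AT4G28140, PDF1.2b and AT5G15660 lost the call in at least 1 case, with adjusted p-values of up to 0.132, 0.122, 0.112, 0.104, 0.0935 and 0.0501.

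In the abscisic acid and dehydration list 4 of 6 genes were lower under 4'-OH-2,5-DCB (4 adjusted over the list alone), with a median of -2.36 and a camera adjusted p of 2.41e-07 (adjusted p = 0.211 with an estimated correlation). KIN1 had -0.24 and LTI30 -1.05, neither past the threshold. The xenobiotic list had 1 of 4 genes higher, UGT73B4 at 1.51 (2 adjusted over the list alone), with a camera adjusted p of 0.045 (adjusted p = 0.410 with an estimated correlation, and 0.079 after quantile normalization). It was 0.0732 and 0.141 without control replicate 2 or 3, 0.0547 without 2,5-DCB replicate 3, and 0.221 and 0.146 without replicate 2 or 3 of 4'-OH-2,5-DCB. The light harvesting and photosystem list had 0 of 8 called, also adjusted over the list alone, and a median of -0.56, with a camera adjusted p of 0.00213 (adjusted p = 0.429 with an estimated correlation). Its median was -0.29 without 4'-OH-2,5-DCB replicate 1. Of 55 UDP-glycosyltransferase genes 5 were higher and 0 lower (6 and 1 adjusted over the list alone), among them UGT72E2 (2.02), UGT84A4 (1.01) and UGT76B1 (0.90). The list did not pass (camera adjusted p 0.244). With 1 array left out it passed only without control replicate 1 (camera adjusted p 0.0469). It also passed with fry in place of camera (adjusted p 0.0415).

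Of the other lists, the tau and phi glutathione S-transferases and the P450 genes had 0 called of 11, 3 and 24 tested (3, of which 2 higher, 0 and 0 adjusted over the list alone). The 24 P450 genes are again those tested of 240. The tau list did not pass with camera (adjusted p 0.25) but passed with fry (adjusted p 0.0137). GSTU25 had a log2 change of 1.57 with an adjusted p of 0.0709. The auxin list had 1 of 9 lower, WES1 (-1.61), and the expansin list 1 of 28 lower, EXPA20 (-1.04). Adjusted over the list alone, 1 auxin gene was higher and 2 lower, and 2 expansin list genes were higher and 3 lower. With that group's replicate 1 left out, 2 tau genes, 2 expansin list genes and 2 xenobiotic response genes were higher, and 1 gene each of the P450, expansin, unfolded protein response and flower lists was lower. The auxin median, 0.19, was above 0 with its mean, -0.18, and the test below, and the P450 median and mean were above 0 with the test below. The unfolded protein response had a median of 0.16, a mean of -0.12 and a test above 0. With 1 array left out these medians ranged from 0.0385 to 0.397 (auxin), -0.0663 to 0.133 (P450) and -0.0917 to 0.56 (unfolded protein response). Root markers had 1 of 4 higher, the beta-glucosidase gene PYK10 (1.11), with a camera adjusted p of 0.0840, and flower markers and the unfolded protein response had 0 of 3 each (1, 0 and 2 called adjusted over the list alone). The root and flower marker lists were fixed as a check of tissue make-up. With so few tested genes they cannot settle whether the share of roots in the whole plants differed between the groups, under either exposure. Among genes of smaller lists, DFR, of anthocyanin synthesis, rose by 0.96, PORB, of chlorophyll synthesis, fell by 1.39 and AT5G52050 fell by 2.17.

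The count of 486 was 1197 without 4'-OH-2,5-DCB replicate 1 (571 higher and 626 lower), and 483 of the 486 were among these. It was 246 without replicate 2 of that group, 200, 93 and 168 without control replicate 1, 2 or 3, and 319, 259 and 255 without 2,5-DCB replicate 1, 2 or 3. With only the 6 arrays of the groups compared it was 98. The excess of falls was larger after quantile normalization (214 higher and 642 lower), and rises outnumbered falls with array weights (923 and 904). They also did with all probe sets (644 and 560), where repeated values among unnamed probe sets were counted. Of the unnamed, 745 were called but only 505 distinct rows of values (262 higher and 243 lower), so the repeats weigh on that balance.

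**Figure D2:**
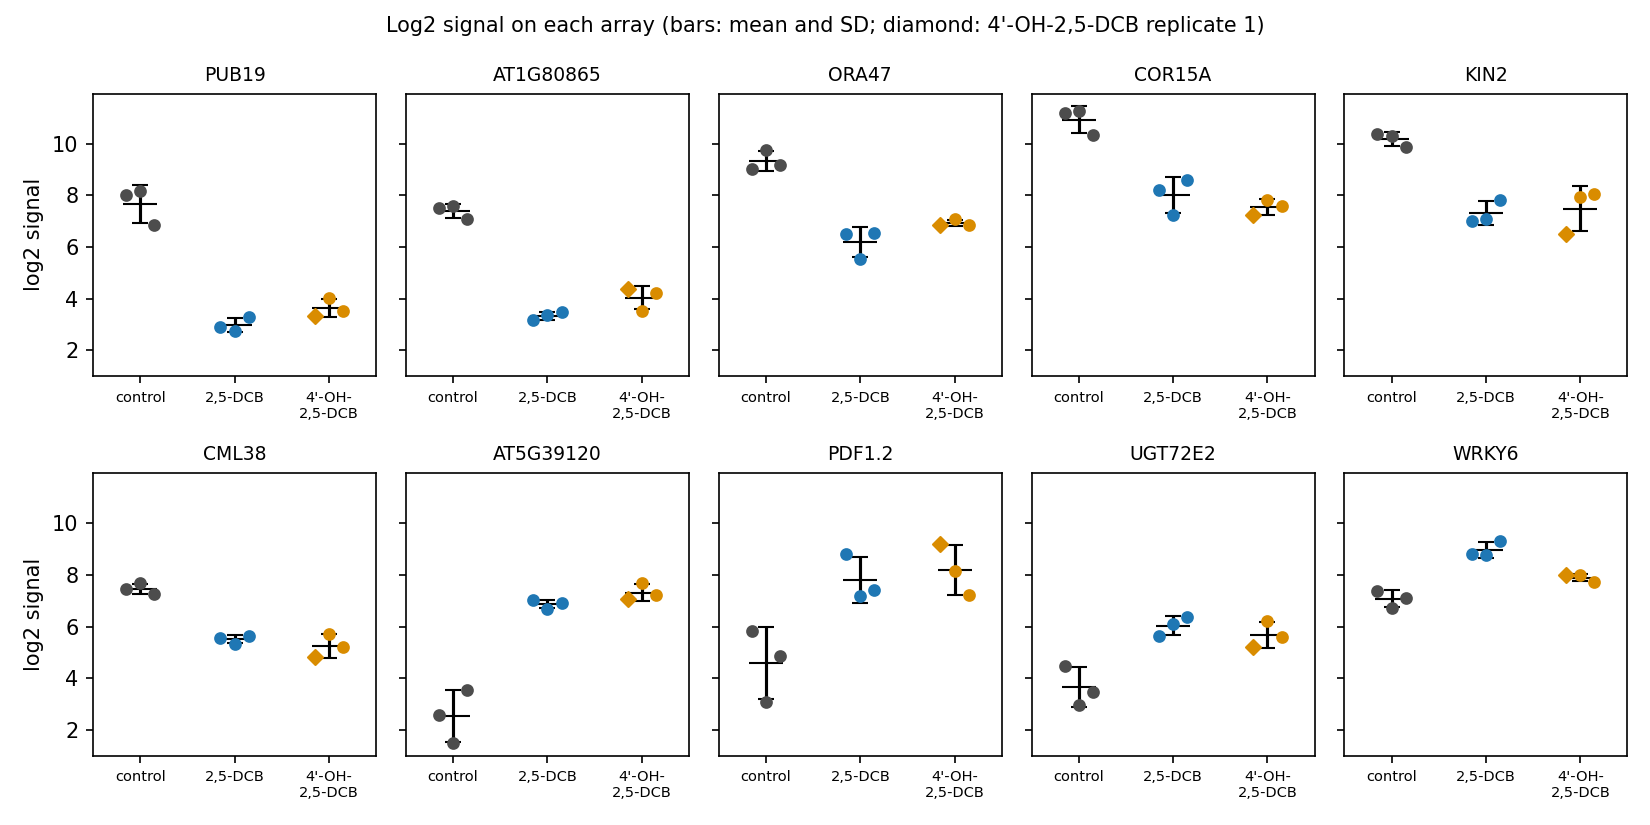
Log2 signal of 10 genes on each array, by group (points, arrays; bars, mean and SD; diamond, 4'-OH-2,5-DCB replicate 1). All 3 arrays of each exposed group lie below the controls for PUB19 and COR15A, and above them for AT5G39120.

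The last comparison set the exposures against each other. Among the smallest p-values were those of AT4G12290, at 8.13 ± 0.33 under 2,5-DCB and 6.03 ± 0.36 under 4'-OH-2,5-DCB, and of AT3G55240, at 6.01 ± 0.51 and 8.16 ± 0.09. Neither passed: the difference, 4'-OH-2,5-DCB minus 2,5-DCB, was -2.10 (95% interval -2.63 to -1.58, adjusted p 0.0521) and 2.15 (1.56 to 2.75, adjusted p 0.0569). None of the other genes with the smallest p-values passed. Of these, AT4G16146 (-1.71), AT1G56300 (-2.67), AT5G57655 (-1.47) and PPDK (-1.34), the pyruvate orthophosphate dikinase gene, had lower values under 4'-OH-2,5-DCB. Higher values there were those of AT5G09480 (1.38), AT4G13960 (1.24), AT4G13575 (1.17) and AT2G43610 (1.09). In each group the mean of AT4G13960 lay below the 25th percentile of that group's arrays. Its difference may therefore lie in background and is uncertain. Of genes called in both groups, PUB19 differed by 0.65 (-0.14 to 1.43), COR15A by -0.46 (-1.30 to 0.37) and PDF1.2 by 0.40 (-1.26 to 2.07). Without 4'-OH-2,5-DCB replicate 1 these differences were 0.788, -0.302 and -0.099, so that of PDF1.2 turned. The unadjusted intervals of COR15B (-0.78, -1.27 to -0.30), UGT76B1 (-0.99, -1.41 to -0.57) and AT5G26260 (1.22, 0.57 to 1.87) left out 0, and their adjusted p-values were 0.261, 0.139 and 0.223. In limma 0 probe sets passed, while 1656 had an unadjusted p under 0.05, where 836 are expected by chance. The count was 63 without 4'-OH-2,5-DCB replicate 1, where the 10 genes named for this contrast passed (adjusted p 0.0121 to 0.0348), and 9 with trend and robust options.

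The tau glutathione S-transferase list, of enzymes that conjugate glutathione to foreign compounds, was higher under 4'-OH-2,5-DCB than under 2,5-DCB, with a median difference of 0.33 over 11 genes and a camera adjusted p of 0.045 (adjusted p = 0.336 with an estimated correlation). No member passed by itself, also adjusted over the list alone, and the list did not pass after quantile normalization (median 0.221, adjusted p 0.118) or median centring (0.255 and 0.064). The adjusted p was 0.056 and 0.0557 without control replicate 2 or 3, 0.0905 and 0.0582 without 2,5-DCB replicate 1 or 3, and 0.221 and 0.123 without 4'-OH-2,5-DCB replicate 2 or 3. The expansin and xyloglucan hydrolase list had a median difference of 0.32 over 28 genes and a camera adjusted p of 0.0108 (adjusted p = 0.411 with an estimated correlation), with 0 called adjusted over the list alone. Without 4'-OH-2,5-DCB replicate 1 this median was 0.04 and the adjusted p 0.146.

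Set side by side, 236 probe sets were lower and 63 higher in both exposed groups, and 0 were called in opposite directions. Without 4'-OH-2,5-DCB replicate 1 these were 491 and 291. Independent lists of these sizes would share 8.98 and 3.06, a reference that leaves out the shared controls. PUB19, AT1G80865, COR15A, COR15B, KIN2 and CML38, a calmodulin-like gene, are among those lower in both, and AT5G39120, AT5G39110, PDF1.2 and UGT72E2 among those higher in both. Across probe sets the log2 changes had a Pearson r of 0.685, against 0.500 in the simulations. Their covariance was 0.163, against 0.0453 from the shared controls, a difference of 0.118. With the spread of the control arrays alone, a choice made after seeing the data, the shared part was 0.0217. The controls could not be split, so part of the excess in the counts may come from them. The moderated F-test over the 3 groups called 670 probe sets. Without 4'-OH-2,5-DCB replicate 1 the probe sets called in both were 782 and the F-test count was 2074, and without control replicate 2 they were 64 and 114.

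**Figure D3:**
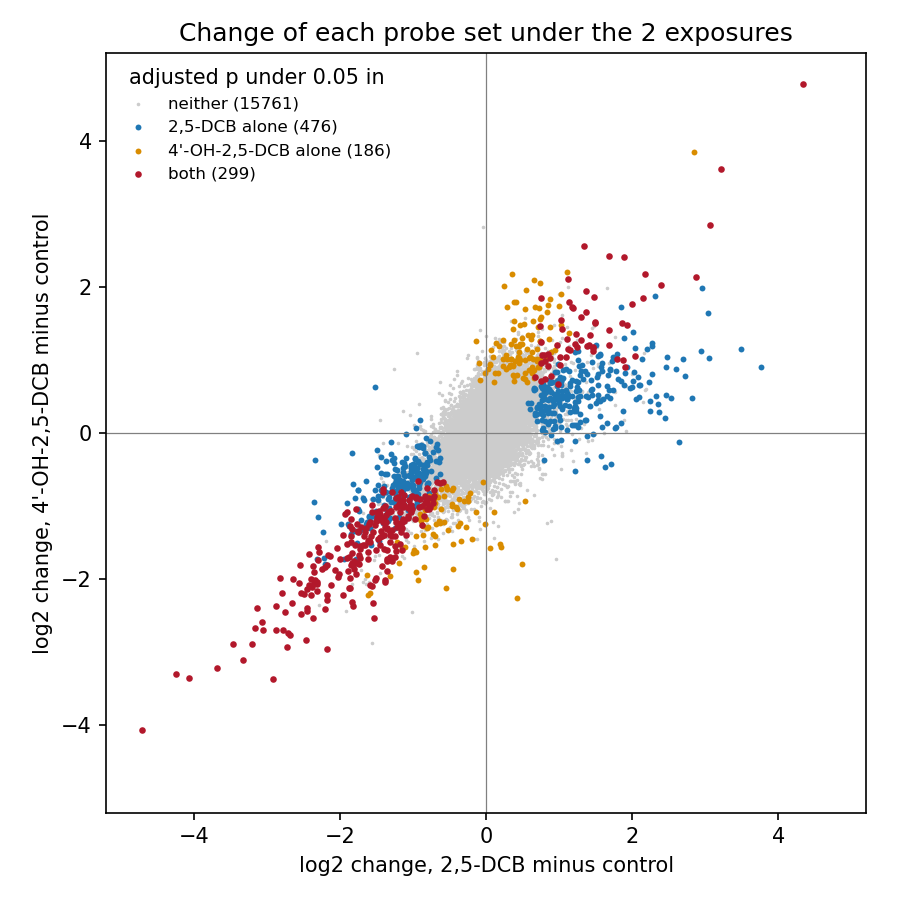
Log2 change of each tested probe set under 2,5-DCB (horizontal axis) and under 4'-OH-2,5-DCB (vertical axis), both against control; colours show in which comparison it was called. The 299 probe sets called in both lie in the lower left (236) and upper right (63).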

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

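The tests of the signal range, of the place of 1 array between the groups and of the lists between the exposures were chosen only after the results had been seen. A difference between the exposed groups drew attention in 2 gene lists, and calls among probe sets without a gene name drew attention outside the main measurement. Of the unnamed probe sets, 597 distinct rows of values were called under 2,5-DCB and 505 under 4'-OH-2,5-DCB, when all probe sets were fitted together.

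The array of 4'-OH-2,5-DCB replicate 1 stood apart: its deviation from the other arrays of its group fell with the signal level (Pearson r = -0.678 across probe sets, against -0.262 to 0.164 on the other arrays). This largely follows from its narrower SD, so it describes a compressed signal range and is no separate test of it. At 65% of 1197 probe sets (95% binomial interval 62.2 to 67.7) it lay closer to its own group than to the controls. At 52.4% of 63 (39.4 to 65.1) it lay closer to its own group than to 2,5-DCB. These intervals treat probe sets as independent, which they are not, so they are too narrow, and the compression itself moves the shares. Neither share was over the 65% set beforehand as the bound against a wrong label, so the shares do not decide. With the trend with level removed, the place of this array over the same probe sets was 0.867 on a line from the control mean (0) to the other arrays of its group (1), where control arrays reached at most 0.224. It was 0.681 from 2,5-DCB (0), where 2,5-DCB arrays reached at most 0.272. These places, a measure chosen after the results had been seen, argue against a control or a 2,5-DCB array under a wrong label. No biological explanation was tested.

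The tau glutathione S-transferase and the expansin and xyloglucan hydrolase lists had median differences of 0.328 and 0.317 between the exposures. The values argue against the narrow range of that array for the tau list (median 0.283 and adjusted p 0.0261 without it), while it may account for the expansin list (0.0441 and 0.146). Quantile normalization and median centring lowered the tau median to 0.221 and 0.255 (SD over members 0.355 as deposited, 0.356 and 0.355 after), with 10, 10 and 9 of 11 members above 0. The call ended with each (adjusted p 0.118 and 0.064, from 0.045 as deposited) and also with an estimated correlation (0.336) and without each of 6 single arrays (0.0557 to 0.221), and why was not tested. Centring moves all genes alike, so the lower median after it is not particular to this list, and the compound and its dose, which the design does not separate, stay open.

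Other groupings of the arrays were tried for each count. For 2,5-DCB against control the real grouping called 777 probe sets and the highest of the other 9 called 0, for 4'-OH-2,5-DCB 486 and 0, and between the exposures 0 and 0. In these comparisons 1, 1 and 10 of the 10 groupings gave as many calls as the real one, and 10 groupings are too few for a share under 0.05. For the 3 groups together, 1 of 100 groupings drawn, the real one, gave as many as 670, and the highest other gave 442. The values argue against a random grouping of these arrays as the source of that count. Whether arrays of a group share plants or boxes is not known, so regrouping cannot tell the exposures from such a shared source.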

How the results depend on the processing

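The alternatives were chosen before the data were examined, except for 5 that are named as such where given. Directions held for the genes named in the contrasts by size or smallest p-value, list members aside. This covers 442 values under other settings and 450 with an array left out, of which 15 and 52 lost and 42 and 10 gained a call. For each such gene the arrays of the groups compared did not overlap. Neither leaving out an array nor array weights could therefore turn its direction, and of the other settings only the rescalings alter the log2 change. The cause of the changes below was not tested, except that fewer arrays entered where one was left out. Counts are given in the order 2,5-DCB, 4'-OH-2,5-DCB, between the exposures, and the 3 groups together. Counts within 1.5 times of the main ones are left out, except for the replicate block and the list calls.

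With quantile normalization the last 3 were 856, 17 and 1061, and the overlap of lists was 496. It shifted the median log2 change of all probe sets by -0.08 and -0.14 under the 2 exposures, and median centring by less than 0.1. Between the exposures 21 and 17 were called after the filters at the 25th and 50th percentile, 9 with trend and robust options, and 263 at an unadjusted p with a change of at least 2-fold. With all probe sets the counts were 1317, 1204 and 1166 for the first, second and last, repeated values among unnamed probe sets included. With only the groups compared, the first 2 were 1725 and 98. With array weights, where 4'-OH-2,5-DCB replicate 1 had a weight of 0.065, they were 2450, 1827, 349 and 2738, with an overlap of 1103.

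The arrays share only a replicate number. Same-numbered arrays had correlations of deviations from -0.247 to 0.0742, and 0 of 9 arrays correlated best with its own number. With the replicate block the counts were 397, 238, 0 and 270, the overlap 146, the correlation 0.685 and the list calls 9.

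With 1 array left out the counts ranged from 181 to 2161, from 93 to 1197, from 0 to 63 and from 114 to 2074. The overlap ranged from 64 to 782, the correlation from 0.587 to 0.743 and the list calls from 6 to 11. For the first, second and last counts and the overlap, the lowest came without control replicate 2, and for all 4 counts and the overlap the highest without 4'-OH-2,5-DCB replicate 1. Without the latter, the light harvesting list between the exposures turned from -0.06 to 0.213 (range with 1 array left out, -0.221 to 0.213), and its camera adjusted p from 0.696 to 0.0261. The correlation was 0.754 after the filter at the median. Of 9 list calls, 0 held with an estimated correlation. With fry the list calls were 10, and after quantile normalization and median centring 7 and 8. Fry ended the light harvesting call under 2,5-DCB (adjusted p 0.15). It gave calls for the tau and UDP-glycosyltransferase lists under 4'-OH-2,5-DCB (adjusted p 0.0137 and 0.0415). Chosen after seeing the data, lists with 1 or more genes gave 11 calls, and plastid-encoded genes kept in the lists gave 9. Signal over background is not given in the values used here, so dim probe sets could not be told from absent ones.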

Other observations

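The tests in the first paragraph were chosen only after the data had been seen. In a scan of 54 families by symbol, 14 of 162 tests passed with the preset correlation and 0 with an estimated one (adjusted p of 0.748 for each of the families named here). The jacalin-related lectin genes had a median log2 change of 1.02 over 5 genes under 4'-OH-2,5-DCB (camera adjusted p 0.00281) and of 0.62 under 2,5-DCB (0.0265, and 0.106 without 4'-OH-2,5-DCB replicate 1), and JAL22 (1.01) rose under 4'-OH-2,5-DCB and JAL31 under both (0.98 and 0.81). Genes whose symbols start with PDF had medians of 0.49 and 0.94 over 10 genes under 2,5-DCB and 4'-OH-2,5-DCB (adjusted p 0.00799 and 0.00456, the first being 0.118 without 4'-OH-2,5-DCB replicate 1). That prefix joins plant defensins with the peptide deformylase genes PDF1A and PDF1B, which were not called, and PDF1.4 rose by 2.60 under 2,5-DCB. The IQD genes, of calmodulin-binding proteins, had a median of -0.34 over 17 genes under 2,5-DCB (adjusted p 0.0316), and iqd21 fell by 1.25. Of the 14 calls, only 3 held without 4'-OH-2,5-DCB replicate 1. These were the lectin and PDF genes under 4'-OH-2,5-DCB and the IQD genes under 2,5-DCB (camera adjusted p 0.00322, 0.0387 and 0.0387). All calls between the exposures ended (0.131 to 0.892).

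Of 6 cold and dehydration genes 5 were lower under 2,5-DCB and 4 under 4'-OH-2,5-DCB (adjusted p = 0.211 for the list in both with an estimated correlation), and handling of the plants at harvest is a candidate explanation. A list of 26 rapid touch and wound genes was written after the largest changes had been seen but before its own test, and 3 of them are named on the array. Their median log2 change was -0.866 under 2,5-DCB and -0.837 under 4'-OH-2,5-DCB, past the bound of -0.5 that had been set, with camera adjusted p-values of 0.000952 and 0.0018 (adjusted p = 0.260 in both with an estimated correlation). CML38 fell by 1.95 and 2.22, CML37 fell by 0.87 under 2,5-DCB, and STZ did not pass; without 4'-OH-2,5-DCB replicate 1 the medians were -0.866 and -0.413, the latter short of the bound, with unadjusted camera p-values of 4.6e-05 and 0.000879. Harvest at another time of day cannot be told apart, since GI, at 0.282 and -0.930, is the only clock gene of those listed that is named here, and an effect of the exposures themselves also stays open.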
